A study of Neurospora crassa OR74A with 13 samples.

How the data were processed

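Polyadenylated RNA was measured by Illumina sequencing in 13 libraries of Neurospora crassa. Per the labels' protocols, mycelia were pregrown for 16 h in sucrose medium from 1000000 conidia per mL, washed, and shifted for 4 h to Avicel (crystalline cellulose), cellobiose, sucrose or no carbon source. Messenger RNA was taken on oligo-dT beads, fragmented with zinc and primed with random primers, per the same protocols. The wild type (WT) was compared with a strain called TBGK, which lacks 3 beta-glucosidase genes (gh3-4, gh1-1 and gh3-3). The labels describe the WT libraries on Avicel, sucrose and no carbon as biological triplicates and mark these 9 libraries as shared with an earlier deposit. The WT on cellobiose and TBGK on Avicel, cellobiose and sucrose had 1 library each.

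The deposited values were FPKM (fragments scaled by transcript length and library size), made with TopHat and Cufflinks 0.9.3 per the submitters' processing notes, which give no TopHat version. The genome build was not given in the sources used here, and positions are those of the contigs named in the deposited files. FPKM was deposited for 9907 transcripts in the triplicate libraries, which were summed to genes here, and for 9733 genes in the single libraries. All 9733 genes occurred in every library. Per the file headers, the triplicate files also hold coverage (mean read depth per base), transcript lengths and the fraction of each gene's isoforms. The sum of FPKM times effective length was 5.23 to 9.28 times the value that scaling by the total reads on these transcripts would give, so another divisor was used. In replicates 1, 2 and 3 this factor was 5.23, 5.45 and 5.36 on no carbon, 7.81, 6.02 and 6.21 on Avicel and 7.76, 9.02 and 9.28 on sucrose. It thus differed with the carbon source, and small differences between these groups depend on the scaling. Coverage divided by FPKM was constant within each triplicate library and gave its depth in aligned megabases. The depth of the 4 single libraries is unknown, because their deposited tables hold no coverage. Whole read counts could not be recovered, so no counting interval or limit for a value of 0 is given. The deposited FPKM confidence bounds equalled FPKM plus or minus a multiple of its square root for 85.5% to 89.8% of entries and were not used, nor were the isoform fractions. Symbols came from a reference gene table of assembly NC12, which matched 9016 of the 9733 identifiers and gave 1106 a symbol; none of its coordinates is printed.

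The 3 comparisons among the WT triplicates were fitted together on 9 libraries with limma 3.58.1 (moderated test with intensity trend) in R 4.3.3. Values were log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were kept, which left 8759. A gene with a Benjamini-Hochberg adjusted p under 0.05 was called, and rose, fell and changed are used only for calls. Log2 differences are given with the standard error (SE) of limma and means of FPKM with the standard deviation (SD, n = 3); p-values refer to the spread between biological replicates. The test was checked on simulated data with the mean and residual spread of 8759 genes over all 9 libraries. For Avicel against no carbon it recovered 69 of 100 genes changed by 2 log2 units and 96 of 100 changed by 5. Unchanged genes, 7 in number, made up 4.07% of its calls. The simulated noise was independent between genes, whereas 49.5% of the real residual variance lay on 1 shared component. The real shares may therefore differ. The Avicel-induced set holds the genes called higher with a fold of at least 2 in both Avicel comparisons. Comparisons with a single library had no test. Their difference in log2(FPKM + 1) was computed per gene (replicates averaged on the log scale), genes with a fold of at least 2 were counted as higher or lower, and the median of a list was placed among 10000 random lists matched on mean expression, as a description of those libraries. As an alternative, limma was fitted over all 13 libraries with the single ones assumed to vary like the WT triplicates. That model also gave the strain by carbon source interactions. Where a single library is compared with WT triplicates, a difference between deposits cannot be told apart from the effect of strain or carbon source. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.

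Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over all lists and the 3 comparisons, and again with an estimated correlation and with fry. The 13 lists fixed beforehand were cellulases, lytic polysaccharide monooxygenases, cellobiose utilization, hemicellulases, pectin degradation, starch degradation, regulators, hexose transport and sucrose cleavage, glyoxylate cycle and gluconeogenesis, glycolysis and fermentation, endoplasmic reticulum (ER) folding, conidiation, and light response. Another 8 lists planned by product name could not be built, since no table gave product names. In their place 10 lists were made from gene symbols after the data were seen: respiratory complex I, proteasome, heat shock proteins, cytosolic ribosomal proteins, mitochondrial import, peroxins, histones, the qa cluster, amino acid biosynthesis and chitinases. Since only 1106 genes had a symbol, these 10 lists can lack many members of their class, and counts refer to the listed genes. The identifiers NCU00972, NCU08412, NCU06326 and NCU09235 of the fixed lists were absent from the files. Named genes follow a rule: the 3 deleted genes and clr-1, clr-2, xlr-1 and cre-1 throughout; all cellulases and up to 4 called members per list with the largest changes; the 6 largest rises and falls per WT comparison among called genes whose replicate ranges do not overlap and whose higher mean FPKM is at least 10; and the 5 largest differences each way in single-library comparisons. Other genes are named as chosen after values were seen.

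The design, the tests, the 13 lists, the naming rule and the alternatives that follow were set before the data were examined. These alternatives were a pseudocount of 0.1 or 5, no filter or an FPKM of at least 5, median-of-ratios scaling, quantile normalization, a replicate block, limma without trend, each replicate left out in turn in the comparisons among the WT triplicates, only the 6 libraries compared, a fold minimum of 4, and a set defined by a fold of 4. Fits without the 2 shallowest libraries or with the first principal component of the residuals as a covariate, single-library comparisons and interactions with each WT replicate left out, with only the WT library that stood apart or without the deleted genes, and the comparisons of TBGK on cellobiose with TBGK on Avicel and of TBGK with WT on Avicel, were chosen after seeing the data. The authors' cluster tables named in the deposited readme were not analysed here.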

Results

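Transcript levels were measured in 13 libraries in 7 groups. The WT on Avicel, on no carbon and on sucrose had 3 biological replicates each, and WT on cellobiose, TBGK on Avicel, TBGK on cellobiose and TBGK on sucrose had 1 library each. Depth, as aligned megabases in replicates 1, 2 and 3, was 472, 2324 and 2201 for Avicel, 2102, 5525 and 5640.4 for no carbon, and 480.1, 2149.9 and 1942 for sucrose, an 11.96-fold range. The depth of the single libraries is unknown. Between 718 and 2341 of the 9733 genes were listed at 0 in a library, with the most in sucrose replicate 1, and the median FPKM was 70.9 to 92.7.

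The 3 genes deleted in TBGK, which encode beta-glucosidases that split cellobiose into glucose, were near 0 in every mutant library. For gh1-1 (NCU00130, supercont10.3, 2730965 to 2732948), which encodes an intracellular enzyme, FPKM was 9.21 in TBGK on Avicel, 7.47 on cellobiose and 1.80 on sucrose. The WT had 33410.4, 43047 and 50743 on Avicel, 2632 on cellobiose, 158, 204 and 205 on no carbon, and 13.2, 47.1 and 16.0 on sucrose. For gh3-3 (NCU08755, supercont10.3, 5254974 to 5258174), FPKM was 0, 3.36 and 0 in TBGK on Avicel, cellobiose and sucrose. The WT had 3441, 11177 and 11578 on Avicel, 3254 on cellobiose, 463, 262 and 452 on no carbon, and 2.28, 10.1 and 2.82 on sucrose. For gh3-4 (NCU04952, supercont10.4, 846340 to 849048), TBGK had 3.23 on Avicel, 1.66 on cellobiose and 1.09 on sucrose. The WT had 1827, 189 and 224 on Avicel and 61.1, 67.6 and 98.2 on no carbon, but 1.36 on cellobiose and 0, 0.983 and 0 on sucrose. The gh3-4 transcript therefore told the strains apart on Avicel only, gh1-1 and gh3-3 on Avicel and cellobiose, and on sucrose the WT levels were low for all 3.

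**Figure D1:**
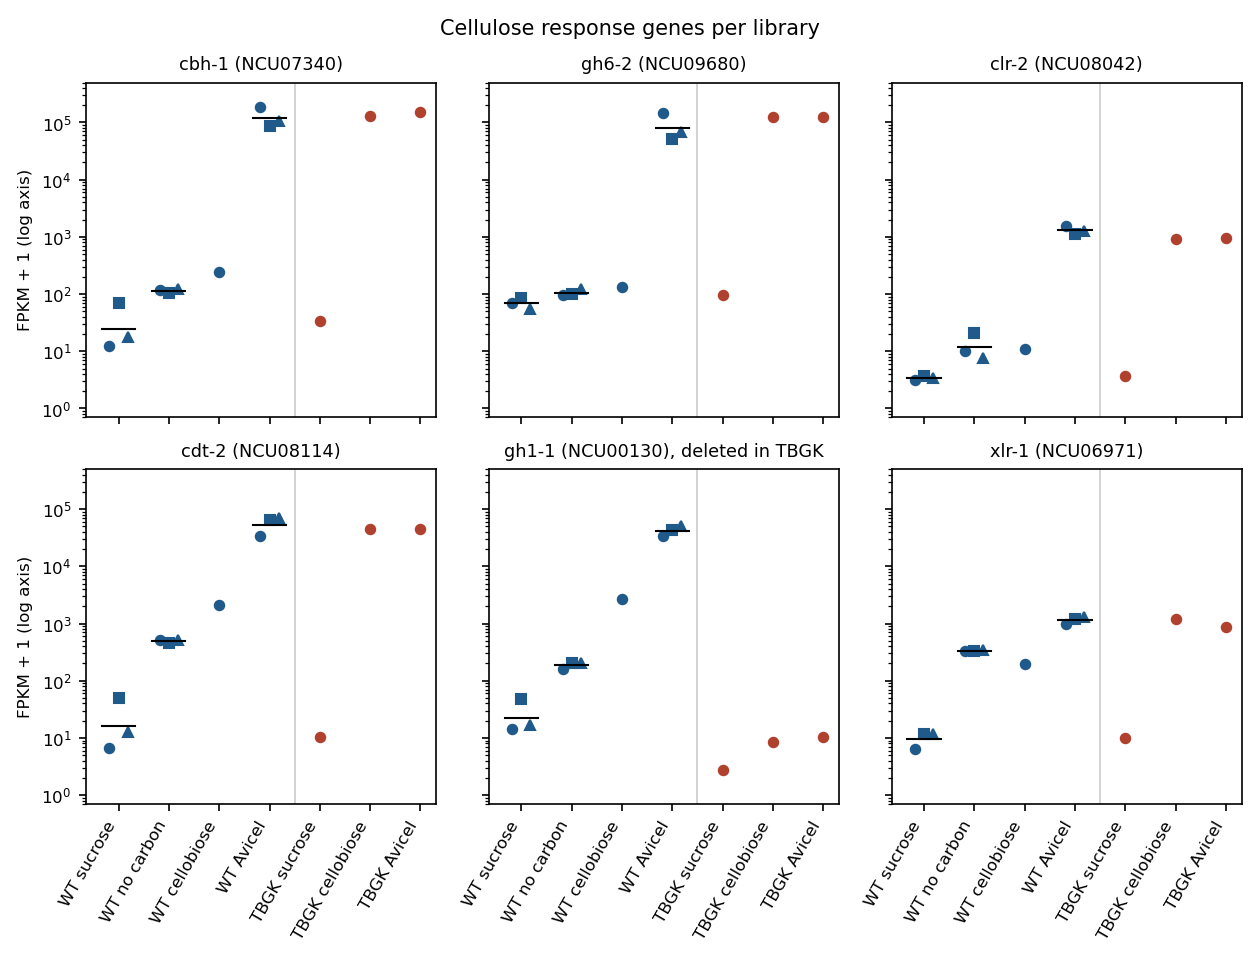
FPKM + 1 on a log axis in each library for cbh-1, gh6-2, clr-2, cdt-2, gh1-1 and xlr-1, with WT in blue, TBGK in red, 1 point per library and a black line at the mean of the log values of 3 replicates. TBGK lies at an FPKM of 9.21 or lower for gh1-1, and clr-2 lies at 936 in TBGK on cellobiose but at 10.2 in WT on cellobiose.

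The comparison of WT on Avicel with WT on no carbon asked which transcripts respond to cellulose itself rather than to the loss of sugar. Among the genes that rose were parts of the machinery that takes crystalline cellulose apart: cellobiohydrolases and endoglucanases that cleave the chains, lytic polysaccharide monooxygenases (LPMOs) that oxidise them, and xylanases and other hemicellulases. With them rose the transporters cdt-1 and cdt-2, which import cellodextrins, and beta-glucosidases that finish the digestion. The transcription factors that drive this program also rose, as did the ER chaperones that fold secreted proteins. Of 8759 genes tested, 342 rose and 151 fell (limma with Benjamini-Hochberg adjustment), 292 and 112 of them by at least 2-fold, and 1697 had an unadjusted p under 0.05. The total of 493 was 307 without Avicel replicate 2, 276 without Avicel replicate 3, 310.0 without no carbon replicate 1 and 284 without no carbon replicate 3. In fits chosen after seeing the data it was 908 without the 2 shallowest libraries (530.0 rises and 378 falls) and 1135 with the first residual component as a covariate (507 rises and 628 falls). The excess of rises therefore depended on the fit.

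Among the 8 cellulases, 7 rose and gh45-1 (NCU05121) did not pass (3.39 log2, adjusted p = 0.106); adjusted over the list alone, all 8 rose. The cellobiohydrolase cbh-1 (NCU07340), the most abundant transcript of the first Avicel library, rose from 114 ± 9.76 to 125864 ± 53336 FPKM, by 10.02 log2 (SE 0.59, adjusted p = 2.17e-05). The second cellobiohydrolase, gh6-2 (NCU09680), rose by 9.59 (SE 0.36, adjusted p = 1.2e-06), and gh5-1 (NCU00762), an endoglucanase, by 11.66 (SE 0.97, adjusted p = 0.000197). The remaining members gh6-3, gh7-1 and gh7-2 rose by 8.95, 8.69 and 5.72, whereas the call of gh7-4 (NCU05104, 1.89 log2, adjusted p = 0.0383) was lost with any of 7 libraries left out, up to an adjusted p of 0.115 without no carbon replicate 1. Of the 14 LPMO genes 9 rose (10 adjusted over the list alone) and 5 did not pass. The largest rise of all tested genes was that of the LPMO gh61-4 (NCU01050), from 1.82 ± 1.57 to 29968 ± 16788 FPKM (13.47 log2, SE 1.04, adjusted p = 0.000128). Of 24 hemicellulases 19 rose (20 adjusted over the list alone), among them the xylanases gh10-1 (NCU05924, 11.41 log2, adjusted p = 7.5e-05) and gh11-2 (NCU07225, 9.36, adjusted p = 0.0025). NCU04870, which carries no symbol, rose from 5.87 ± 2.17 to 7119.6 ± 2162 FPKM, and gh61-7 (NCU00836) rose by 10.00 log2. In each of the genes named as risen in this paragraph, 3 of 3 Avicel libraries lay above all 3 no carbon libraries.

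Genes that import and use the products rose next. Of 12 cellobiose utilization genes 7 rose (8 adjusted over the list alone), including cdh-1 (NCU00206, 9.27 log2), gh1-1 (7.79), cdt-2 (NCU08114, from 495 ± 26.9 to 56478 ± 19678 FPKM, 6.76 log2) and cdt-1 (NCU00801, 5.62). The deleted gene gh3-3 rose by 4.33 (SE 0.58, adjusted p = 0.00295), and gh3-4 did not pass (2.51, adjusted p = 0.117). Of 6 regulators 4 rose (4 adjusted over the list alone). These were clr-2 (NCU08042), which switches on cellulase genes, by 6.80 (SE 0.35, adjusted p = 9.57e-06), its partner clr-1 (NCU07705) by 2.03 (SE 0.25, adjusted p = 0.00192), the xylanase regulator xlr-1 (NCU06971) by 1.78 (SE 0.24, adjusted p = 0.00307) and vib-1 (NCU03725) by 2.40. The carbon repressor cre-1 (NCU08807, 0.06, adjusted p = 0.974) did not pass. All 6 ER folding genes rose, also adjusted over the list alone, with grp78 (NCU03982), the main ER chaperone, at 13687 ± 2109.8 against 1853 ± 278 FPKM (2.88 log2, SE 0.26, adjusted p = 0.000285). Pectin degradation had 3 rises among 6 genes (3 adjusted over the list alone). Amino acid biosynthesis had 4 rises among 48, led by aro-6 (NCU05548, 2.25 log2, adjusted p = 0.00556), an enzyme that opens the aromatic pathway; without Avicel replicate 3 the list had 2.

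The falls formed no list that passed camera with an estimated correlation. NCU07718, which has no symbol, fell from 980.0 ± 255 to 111 ± 26.4 FPKM (-3.12 log2, SE 0.26, adjusted p = 0.000195), and NCU02939 was listed at 0 in all 3 Avicel libraries against 11.5, 8.84 and 11.3 on no carbon. The isocitrate lyase gene acu-3 (NCU04230), which feeds the glyoxylate cycle, fell by 2.31 (adjusted p = 0.00821), the only call among 5 glyoxylate cycle and gluconeogenesis genes (2 fell adjusted over the list alone). None of the 4 conidiation genes or 5 light response genes was called by limma (3 and 2 at an unadjusted p under 0.05); adjusted over the list alone, 3 conidiation genes (con-10, eas and fl) and 2 light response genes fell. Over all genes 1 conidiation gene fell without no carbon replicate 2, and 3 light response genes fell without no carbon replicate 1 or replicate 2. Among 20 peroxins, which build peroxisomes, 2 fell (6 adjusted over the list alone), and leaving out single libraries gave 0 to 4. Starch degradation had 1 rise and 1 fall among 6 genes (also adjusted over the list alone), and glycolysis and fermentation 1 rise among 12 (1 adjusted over the list alone); each of these calls was lost when most single libraries were left out, as in gla-2 (NCU02583) without no carbon replicate 3 (adjusted p = 0.135) and NCU00575 without no carbon replicate 1 (adjusted p = 0.127). Hexose transport and sucrose cleavage had 0 calls of 6 by limma (0 adjusted over the list alone, 1 at an unadjusted p under 0.05), and 1 rise without Avicel replicate 3 or sucrose replicate 1. There were also 0 calls among 29 genes of respiratory complex I (1 unadjusted), 30 of the proteasome (2), 10 heat shock proteins (2), 7 cytosolic ribosomal proteins (0), 18 of mitochondrial import (0), 9 histones (0), 7 of the qa cluster (0) and 9 chitinases (1 unadjusted, and 1 rise without no carbon replicate 1).

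Camera placed 6 lists above other genes with both correlations. Its adjusted p was 8.06e-20 for cellulases (0.0493 with an estimated correlation), 5.44e-15 for LPMOs (0.0238), 3.45e-12 for cellobiose utilization (0.0246), 4.76e-28 for hemicellulases (0.0145), 3.38e-07 for regulators (0.0269) and 6.74e-12 for ER folding (0.0359). Calls for pectin degradation (adjusted p = 0.000116), peroxins (0.00077), amino acid biosynthesis (0.00482), conidiation (0.0245) and light response (0.0243) were lost, with adjusted p of 0.153, 0.304, 0.285, 0.274 and 0.337 with an estimated correlation. The median and the direction of the test differed in sign for starch degradation (median -0.26, mean 0.17, test up), respiratory complex I (median -0.08, test up), cytosolic ribosomal proteins (median -0.02, test up) and chitinases (median -0.09, test up). Under quantile normalization the median changed sign for glycolysis and fermentation (0.24 to -0.18), histones (0.21 to -0.36) and chitinases (-0.09 to 0.01), and under median-of-ratios scaling for cytosolic ribosomal proteins (to 0.05).

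The comparison of WT on Avicel with WT on sucrose set cellulose against the preferred sugar. Nearly the whole set of plant cell wall enzymes, cellodextrin transporters and their regulators rose again, and with them rose 5 of 6 starch degradation genes and all 4 conidiation genes. Of these lists only hemicellulases passed camera with an estimated correlation. Among the genes that fell were 44 of 48 enzymes of amino acid synthesis, the only falling list to pass camera with an estimated correlation, and, in lists that did not pass it, cytosolic ribosomal proteins and genes of mitochondrial import. Of 8759 genes 2965 rose and 2145 fell, 2453 and 1568 of them by at least 2-fold (limma with Benjamini-Hochberg adjustment; 5566 genes at an unadjusted p under 0.05). The median difference of all genes was 0.26, and 58.0% of calls were rises. Quantile normalization moved these to -0.06 and 47.4%, with 2187 rises and 2425 falls, so sizes below are relative to that shift.

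All 8 cellulases rose, also adjusted over the list alone, from cbh-1 (12.23 log2, SE 0.59, adjusted p = 1.06e-06) through gh5-1 (13.16), gh6-3 (10.32), gh6-2 (10.18), gh7-1 (10.03), gh7-2 (7.03) and gh45-1 (6.29) to gh7-4 (NCU05104), which was listed at 0 on sucrose and did not pass under quantile normalization (adjusted p = 0.201). Among LPMOs 11 rose and 1 fell (11 and 1 adjusted over the list alone), though 0 fell without Avicel replicate 1 or 3 or sucrose replicate 2 or 3. Hemicellulases rose in 23 of 24 cases, also adjusted over the list alone, with gh11-2 at 104663 ± 21117 against 24.0 ± 37.2 FPKM (13.76 log2, SE 1.22, adjusted p = 2.41e-05) and gh10-1 at 13.06. Cellobiose utilization rose in 11 of 12 cases, also adjusted over the list alone, with cdt-2 at 11.70 (SE 0.64, adjusted p = 1.92e-06), gh1-1 at 10.85, gh3-3 at 10.53 and gh3-4 at 8.41. Of the regulators 5 of 6 rose, also adjusted over the list alone, and without Avicel replicate 1, 4 rose and cre-1 fell. Among them were clr-2 by 8.57 (SE 0.35, adjusted p = 5.36e-07), xlr-1 from 8.79 ± 2.95 to 1157 ± 161 FPKM (6.93 log2, SE 0.24, adjusted p = 2.68e-07) and clr-1 by 4.06 (SE 0.25, adjusted p = 3.32e-06), while cre-1 did not pass (-1.39, adjusted p = 0.107). The ER folding list rose in full (6 of 6, also adjusted over the list alone), with grp78 at 2.08. Starch degradation rose in 5 of 6 cases, led by NCU08746 (6.78), gh31-3 (4.57) and the glucoamylase gla-2 (3.64), pectin degradation rose in 5 and fell in 1, with gh28-2 (NCU06961) listed at 0 on sucrose and gh28-1 (NCU02369) at -1.86, and both counts were the same adjusted over the list alone. In hexose transport and sucrose cleavage 4 rose and 1 fell (also adjusted over the list alone). The glucose transporter hgt-1 (NCU10021) went from 190.3 ± 98.3 to 5213 ± 275 FPKM (4.95 log2, adjusted p = 1.61e-05), and NCU01633 fell by 3.86. All 4 conidiation genes rose, also adjusted over the list alone, with the spore coat hydrophobin eas (NCU08457) at 7.20 (SE 0.68, adjusted p = 3.41e-05). Of the light response genes 3 rose (3 adjusted over the list alone), including al-1 (NCU00552, 3.56), an enzyme of carotenoid synthesis.

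The falls were widest in amino acid biosynthesis, where 44 of 48 genes fell and 2 rose. The branched-chain enzyme ilv-2 (NCU03608) fell from 15993 ± 3487 to 132 ± 88.9 FPKM (-7.08 log2, SE 0.39, adjusted p = 1.93e-06), and leu-2 (NCU04385) and lys-3 (NCU03010), which act in leucine and lysine synthesis, fell by 6.61 and 5.99. The vitamin B6 gene pdx-1 (NCU06550) fell from 14579 ± 1639.7 to 172 ± 122 (-6.62 log2, adjusted p = 3.95e-06), and NCU03561, without a symbol, fell by 8.72 (SE 0.65, adjusted p = 9.22e-06). All 7 listed cytosolic ribosomal proteins fell, with crp-4 (NCU04331) at -4.54, and so did 18 of 18 mitochondrial import genes, with tim54 (NCU07295) at -4.10. Camera estimated a correlation of 0.97 between the 7, so they are not 7 separate observations. Of 10 heat shock proteins 8 fell, with the mitochondrial chaperonin hsp60 (NCU01589) at -4.46 (SE 0.25, adjusted p = 2.12e-06), and 16 of 30 proteasome genes fell (6 under quantile normalization). In glycolysis and fermentation 7 of 12 fell (also adjusted over the list alone; 3 fell and 1 rose under quantile normalization, and 1 rose without sucrose replicate 1), with the pyruvate kinase gene ace-8 (NCU06075) at -2.53. Glyoxylate cycle and gluconeogenesis had 1 rise, the gluconeogenic fbp-1 (NCU04797, 2.49), and 1 fall, the acetyl-CoA synthetase acu-5 (NCU06836, -1.96), the same adjusted over the list alone; Avicel replicate 3 or no carbon replicate 1 left out gave 2 rises or 2 falls. Peroxins had 2 rises and 4 falls (4 rises without Avicel replicate 1 or sucrose replicate 1), chitinases 5 and 1, the qa cluster 2 rises (4 without Avicel replicate 1, 1 without Avicel replicate 3), histones 1 rise (0 adjusted over the list alone, 0 without Avicel replicate 2 or 3, and 1 fall without sucrose replicate 1) and respiratory complex I 1 rise and 3 falls (0 and 2 adjusted over the list alone, 5 rises without Avicel replicate 1). Under quantile normalization the list median changed sign for the qa cluster (0.59 to -0.14), histones (-0.16 to 0.71) and respiratory complex I (-0.07 to 0.23). In the genes named here and in the preceding paragraph with an adjusted p under 0.05, 3 of 3 Avicel libraries lay on the stated side of all 3 sucrose libraries.

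With an estimated correlation, camera kept hemicellulases (adjusted p = 0.0359) and amino acid biosynthesis (0.0238). The other calls at the preset correlation were lost: adjusted p with an estimated correlation was 0.274 for cellulases, 0.190 for LPMOs, 0.0885 for cellobiose utilization, 0.315 for pectin degradation, 0.239 for starch degradation, regulators and mitochondrial import, 0.285 for ER folding, 0.280 for conidiation, 0.265 for heat shock proteins, 0.369 for glycolysis and fermentation and for cytosolic ribosomal proteins, and 0.606 for the proteasome. Hexose transport and sucrose cleavage (0.204) and light response (0.309) did not pass at the preset correlation either, nor did the glyoxylate cycle and gluconeogenesis (0.712). For the glyoxylate cycle and gluconeogenesis the median was 0.21 and the test pointed down; it lay below 0 without Avicel replicate 1 or 2 or sucrose replicate 2 or 3.

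The comparison of WT on no carbon with WT on sucrose described the response to the absence of a carbon source. All 4 conidiation genes, all 5 light response genes and 4 of 5 genes of the glyoxylate cycle and gluconeogenesis rose. None of these 3 lists passed camera with an estimated correlation (adjusted p = 0.265, 0.458 and 0.869), and only conidiation passed at the preset one (0.0192 against 0.0817 and 0.629). Some enzymes and transporters for plant sugars rose without any cellulose present. Most genes of amino acid synthesis, cytosolic ribosomal proteins and mitochondrial import fell, as on Avicel. Of these falling lists only amino acid biosynthesis passed camera with an estimated correlation. Of 8759 genes 3522 rose and 2111 fell, 2933 and 1543 by at least 2-fold (limma with Benjamini-Hochberg adjustment; 5896 at an unadjusted p under 0.05). The median difference was 0.39 with 62.5% of calls rises; under quantile normalization these were -0.04 and 49.4%, with 2473 rises and 2535 falls.

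All 4 conidiation genes rose, also adjusted over the list alone. The hydrophobin eas went from 202 ± 168 to 116679 ± 77851 FPKM (9.34 log2, SE 0.68, adjusted p = 7.65e-06), con-10 (NCU07325) rose by 9.99 (SE 0.80, adjusted p = 1.32e-05), and con-8 (NCU10997), another gene of spore development, by 10.26. NCU08491 was listed at 0 in every sucrose library against 1238, 1299.6 and 1568 on no carbon. All 5 light response genes rose (also adjusted over the list alone), with al-1 at 4.64 and the photoreceptor vvd (NCU03967) at 3.10. Glyoxylate cycle and gluconeogenesis had 4 rises and 1 fall among 5 genes (also adjusted over the list alone), with fbp-1 at 4.19 (SE 0.52, adjusted p = 0.00015) and acu-5 at -2.31; 2 rises were left without no carbon replicate 2, sucrose replicate 2 or sucrose replicate 3. Starch degradation rose in 5 of 6 cases (also adjusted over the list alone), with gla-2 at 4.32 (SE 0.15, adjusted p = 4.84e-07), and hexose transport and sucrose cleavage had 4 rises, including hgt-1 at 3.91, and 1 fall, NCU01633 at -5.61 (also adjusted over the list alone). Peroxins had 8 rises and 3 falls, and chitinases 6 rises and 1 fall, chit-1 (NCU02184) at -4.43.

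Some genes of the cellulose program also rose on no carbon, where 40.2% of all tested genes rose. Cellulases (adjusted p = 0.180), LPMOs (0.875), regulators (0.463) and pectin degradation (0.475) did not pass camera even at the preset correlation. Cellobiose utilization (0.00609) and hemicellulases (0.00386) passed camera there but not with an estimated correlation (0.239 each). Of 12 cellobiose utilization genes 9 rose (also adjusted over the list alone), with gh3-3 at 6.20 (SE 0.58, adjusted p = 3.03e-05), gh3-4 at 5.90, cdt-2 at 4.94 and gh1-1 at 3.06. Of 24 hemicellulases 18 rose (also adjusted over the list alone; 11 rose and 2 fell under quantile normalization), with gh11-2 at 4.40. Of 8 cellulases 6 rose (also adjusted over the list alone), with cbh-1 at 2.21 (SE 0.59, adjusted p = 0.00967), but 3 rose without no carbon replicate 1 or replicate 3, and 2 rose under quantile normalization. Among LPMOs 6 rose and 4 fell (also adjusted over the list alone), with gh61-6 (NCU03328) at 5.35, and the median of 0.92 was -0.69 under quantile normalization. Pectin degradation had 4 rises and 2 falls (also adjusted over the list alone), and 1 fall when any no carbon library or sucrose replicate 1 was left out. Of the regulators 3 rose and 1 fell (also adjusted over the list alone), with 2 falls without Avicel replicate 1 or no carbon replicate 2. The rises were xlr-1 by 5.15 (SE 0.24, adjusted p = 1.26e-06), clr-1 by 2.04 (SE 0.25, adjusted p = 0.000149) and clr-2 by 1.78 (SE 0.35, adjusted p = 0.00219), which was -0.43 under quantile normalization; vib-1 fell, and cre-1 did not pass (-1.46, adjusted p = 0.089). In eas, con-10, con-8, al-1, fbp-1, gla-2, hgt-1, xlr-1 and clr-1, 3 of 3 no carbon libraries lay above all 3 sucrose libraries.

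In amino acid biosynthesis 44 of 48 genes fell and 1 rose, with ilv-2 at -7.78 (SE 0.39, adjusted p = 1.5e-06), and eth-1 (NCU02657), which makes S-adenosylmethionine, fell from 11614 ± 3599.7 to 77.3 ± 10.2 FPKM (-7.17 log2, SE 0.41, adjusted p = 2.54e-06). All 7 cytosolic ribosomal proteins, 17 of 18 mitochondrial import genes and 8 of 10 heat shock proteins fell, with hsp60 at -5.23. Glycolysis and fermentation had 8 falls among 12 genes (also adjusted over the list alone; 5 falls and 1 rise under quantile normalization, and 1 rise without sucrose replicate 1), with emp-3 (NCU00629) at -2.22. The proteasome had 10 falls (5 adjusted over the list alone, 5 without no carbon replicate 1, no carbon replicate 3 or sucrose replicate 1, and 6 without sucrose replicate 3). ER folding had 1 rise and 2 falls (also adjusted over the list alone; 1 fall without no carbon replicate 1 or replicate 3), and its median of -0.32 was 0.23 under quantile normalization. Respiratory complex I had 4 rises and 5 falls, with a median of -0.05, a mean of 0.01 and a downward test, and quantile normalization moved the median to 0.43. Histones had 1 rise and 2 falls (1 fall adjusted over the list alone, 0 falls without no carbon replicate 2, sucrose replicate 2 or sucrose replicate 3), with a median of -0.40 that was 1.08 under quantile normalization, and the qa cluster had 3 rises (5 without Avicel replicate 1). Camera with an estimated correlation kept amino acid biosynthesis (adjusted p = 0.0238) and lost cellobiose utilization, hemicellulases, starch degradation, heat shock proteins and mitochondrial import (0.239 each), glycolysis and fermentation (0.337), cytosolic ribosomal proteins (0.369), conidiation (0.265) and the proteasome (0.687). Over the 3 comparisons 36 list tests passed at the preset correlation and 9 with an estimated one.

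**Figure D2:**
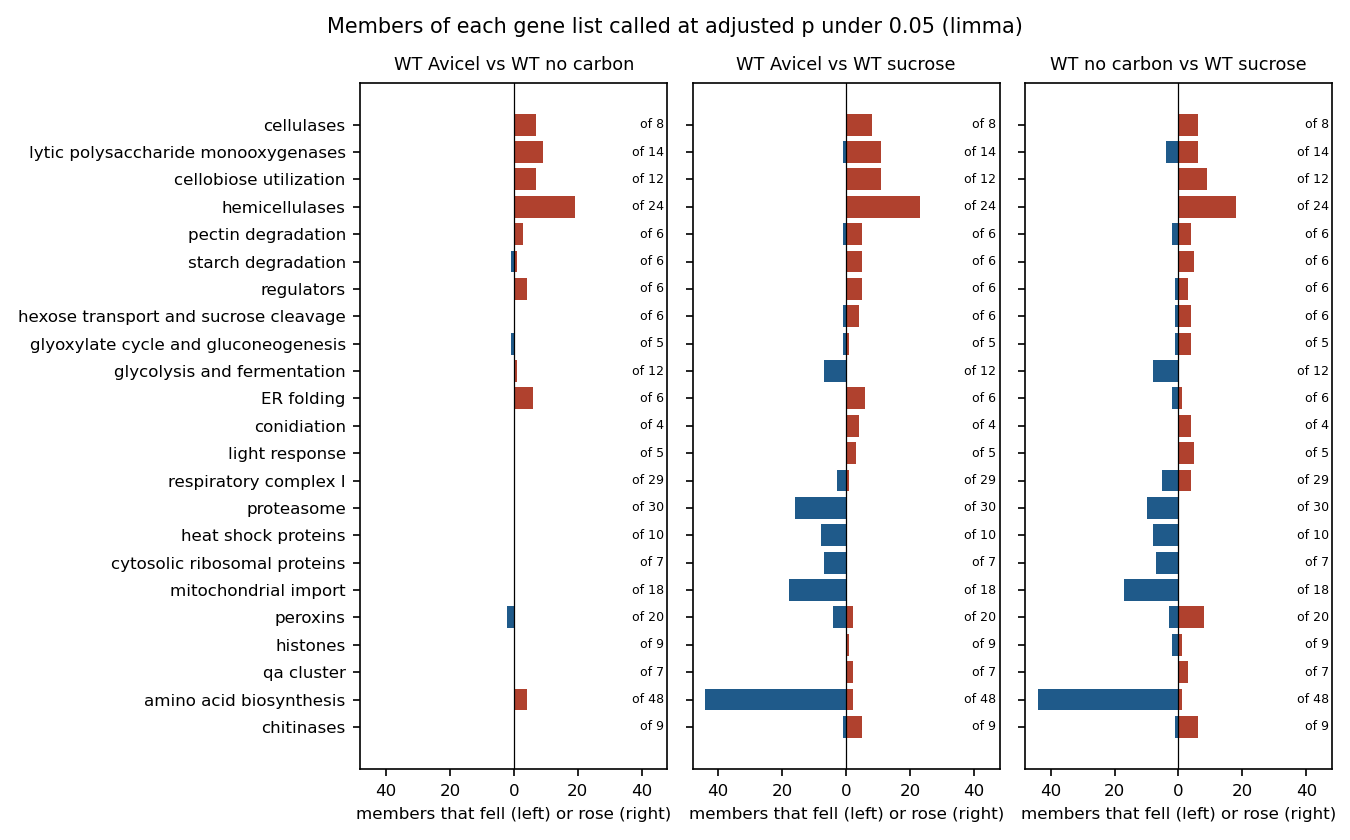
Number of called genes per list in the 3 WT comparisons, with bars to the right for genes that rose and to the left for genes that fell (limma, adjusted p under 0.05). Hemicellulases rose in 19, 23 and 18 of 24 cases and amino acid biosynthesis fell in 0, 44 and 44 of 48, while under quantile normalization the median changed sign for glycolysis, histones and chitinases on Avicel against no carbon, for complex I, histones and the qa cluster on Avicel against sucrose, and for LPMOs, ER folding, complex I, histones and the qa cluster on no carbon against sucrose.

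The Avicel-induced set joined both Avicel comparisons, to separate the response to cellulose from that to starvation, and was fixed before any mutant library was read. It held 213 genes, among them the wall-degrading enzymes cbh-1, gh6-2, gh61-4, gh10-1 and gh11-2, the transporters cdt-1 and cdt-2, the regulator clr-2, the ER chaperone grp78, and gh1-1 and gh3-3 of the deleted genes. Lists of 292 and 2453 rises that were independent would share 81.8 genes. In 100 simulations of unchanged groups that shared the same Avicel libraries the set held at most 0 genes. No gene differed in any simulated group, so these simulations cannot measure the overlap that shared libraries add where many genes differ. Part of the excess may come from the shared Avicel libraries, since 3 libraries cannot be split into parts that each keep at least 2. Since the set was chosen for high values in the WT Avicel libraries and low values in the WT no carbon and sucrose libraries, a comparison of a single library with any of these groups carries that choice, which the random lists do not share. A set that required a 4-fold rise in both comparisons held 135 genes.

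The comparison of TBGK on cellobiose with TBGK on sucrose asked whether cellobiose, which this strain cannot readily split, turns on the genes that cellulose turns on in the WT. Transcripts for nearly the whole enzyme arsenal were higher on cellobiose, together with the cellodextrin transporters and the regulators clr-2 and xlr-1, while most amino acid biosynthesis genes were lower. These values, like all that follow for single libraries, have no replicate check. Of the 213 set genes 185 were at least 2-fold higher, 0 lower and 28 within 2-fold, with a median of 3.22, above all 10000 random lists (percentile 100); of all tested genes, 2612 were higher and 1865 lower. All 8 cellulases were higher (median 10.21), as were 12 of 14 LPMOs, 23 of 24 hemicellulases, 10 of 12 cellobiose utilization genes, 5 of 6 pectin and 5 of 6 starch degradation genes, 4 of 6 regulators and 4 of 6 ER folding genes. The counts for the set and for cellobiose utilization include the deleted genes gh1-1 (7.47 against 1.80 FPKM) and gh3-3 (3.36 against 0). Both stayed near 0 and cannot be read as induced. Without the deleted genes 183 set genes were higher. FPKM of cbh-1 was 130865 against 32.4, of cdt-2 44948 against 9.46, of gh61-4 31766 against 6.31, of clr-2 936 against 2.72, of xlr-1 1193 against 8.88, of clr-1 346 against 49.0 and of cre-1 450.4 against 657. NCU04870 was at 4849.7 on cellobiose and listed at 0 on sucrose, and NCU08785 differed by 12.14. Lower were 42 of 48 amino acid biosynthesis genes (median -2.24), 7 of 7 cytosolic ribosomal proteins and 11 of 18 mitochondrial import genes. The largest decreases with symbols were those of cel-1 (NCU07308, 18.1 against 2040.1), cel-2 (NCU07307, -6.09), which encode the fatty acid synthase subunits, and leu-2 (-5.53).

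In TBGK on Avicel against TBGK on sucrose, which tests whether the mutant still responds to cellulose, the same families were higher. Of the set, 202 genes were higher and 0 lower (median 4.24, percentile 100). The 202 include the deleted gh1-1 (9.21 against 1.80 FPKM), and 201 remained without the deleted genes. All 8 cellulases (median 10.51), 13 of 14 LPMOs, 22 of 24 hemicellulases and 5 of 6 ER folding genes were higher, with cbh-1 at 151613 FPKM, gh11-2 at 13.06 log2 and gh5-1 at 12.67, and 38 of 48 amino acid biosynthesis genes were lower. In a limma model over all 13 libraries, which assumes that the single libraries vary like the WT triplicates, 5 genes responded to Avicel against sucrose differently in TBGK and WT, all with a lower log2 difference in TBGK. That count was 507 without Avicel replicate 1, 227 without sucrose replicate 1, 5 without sucrose replicate 2, 2 without Avicel replicate 3 or sucrose replicate 3, 1 without no carbon replicate 2 or 3 and 0 without Avicel replicate 2 or no carbon replicate 1, so it gives no firm number of genes. The 5 were the deleted gh3-3 (-10.53, SE 1.18, adjusted p = 0.0317) and gh1-1 (-8.98, SE 0.83, adjusted p = 0.0116), and NCU05382 (-6.82), NCU11456 (-4.17) and NCU06153 (-2.97), chosen after values were seen, which were listed at 0 in all 3 WT sucrose libraries and at 6.12, 11.2 and 2.25 FPKM in TBGK on sucrose.

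The comparison of TBGK on cellobiose with WT on Avicel asked how closely the mutant on cellobiose resembles the WT on cellulose. Cellulase transcripts were at about the same level, with 0 of 8 higher, 2 lower and a median of -0.01, and cbh-1 was at 130865 FPKM against 125864 ± 53336. LPMOs were higher in 3 cases and lower in 1 of 14. Hemicellulases were lower in 10 and higher in 3 of 24 (median -0.78), with gh11-2 at 26528 against 104663 ± 21117. Of the 213 set genes 17 were higher and 70 lower (median -0.49, percentile 0), and with each Avicel replicate left out 13 to 23 were higher. Against the range of the 3 WT Avicel replicates, 66 set genes lay inside, 25 above and 122 below. All 7 cytosolic ribosomal proteins were higher (median 1.23), though in crp-4 the Avicel replicates themselves were at 3213, 567 and 558. The largest increases were those of NCU08756 (9.02), which lies next to the deleted gh3-3 and was high in all 3 mutant libraries, and of NCU11874, NCU07159, aod-1 (NCU07953, the alternative oxidase of mitochondria) and NCU04276. Of these, NCU11874, aod-1 and NCU04276 differed widely between WT replicates, with aod-1 at 3444, 24.0 and 18.4 on Avicel. The largest decreases were gh1-1, gh3-3, NCU04169, ccg-4 (NCU02500), a mating pheromone gene, and NCU09968, of which the last 3 were listed at 0. TBGK on cellobiose and TBGK on Avicel, compared after the data were seen, differed in fewer set genes, with 7 higher and 66 lower (median -0.46, percentile 0); 4 of 8 cellulases and 11 of 24 hemicellulases were lower on cellobiose, NCU07159 had the largest increase (5.29), and NCU04169 and NCU06137 were among the largest decreases.

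WT on cellobiose, which can split the sugar, was compared with WT on sucrose and on no carbon to show what cellobiose does in an intact strain. Against sucrose, enzymes of the cellulose program were higher but far below their level on cellulose, next to glucose transporters and starch enzymes that were also higher. Of the set 103 genes were higher and 0 lower (median 0.97, percentile 100). The count of higher genes was 102 to 103 with each sucrose replicate left out and 57 with a fold minimum of 4. Cellulases were higher in 5 of 8 cases (median 1.46), LPMOs in 10 of 14, hemicellulases in 17 of 24, starch degradation in 5 of 6 (median 3.73), hexose transport and sucrose cleavage in 5 of 6 (median 3.98) and conidiation in 4 of 4. The deleted gene gh3-3, intact here, was among the largest increases (9.30), after NCU05897 (9.66), and cbh-1 was at 246 FPKM against 32.7 ± 32.6. Among the largest decreases were ndi-1 (-3.05) and ccg-4 (-2.96). Against no carbon, 34 set genes were higher and 57 lower (median -0.07, percentile 92.0; 35 to 37 higher with each no carbon replicate left out). Of all tested genes 15.8% were higher, about the share of the set (16.0%). Also higher were 39 of 48 amino acid biosynthesis genes (median 2.49), 7 of 7 cytosolic ribosomal proteins and 10 of 12 glycolysis and fermentation genes. Hemicellulases were lower in 13 of 24 cases and higher in 1, cellulases lower in 3 and higher in 2, and conidiation lower in 3 of 4. The LPMOs were higher in 7 and lower in 5 of 14 (median 1.02) and cellobiose utilization genes higher in 5 and lower in 3 of 12 (median 0.44). NCU01633 had the largest increase (8.05), followed by NCU11874 and NCU03561, and con-6 (-8.17) and ccg-4 (-8.95) were among the largest decreases; in NCU11874 the no carbon replicates were at 5.90, 3253 and 7.11.

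The comparison of TBGK with WT on cellobiose set the strains side by side on the same sugar, with 1 library each and with any other difference between the strains included. Transcripts of the cellulase program were far higher in the mutant, and most amino acid biosynthesis genes were lower. Of the set 165 genes were higher and 4 lower, 2 of these deleted genes (median 2.32, percentile 100). All 8 cellulases were higher (median 6.94), as were 11 of 14 LPMOs, 22 of 24 hemicellulases and 4 of 6 ER folding genes, whereas 38 of 48 amino acid biosynthesis genes and 7 of 7 cytosolic ribosomal proteins were lower. FPKM of gh6-2 was 124112 against 131, of cbh-1 130865 against 246, of clr-2 936 against 10.2, of xlr-1 1193 against 193, of clr-1 346 against 156 and of cre-1 450.4 against 1712. The largest increases were NCU04870, NCU08785, NCU08756, gh11-2 and gh6-2, and the largest decreases gh3-3, gh1-1, NCU09968, cel-1 and NCU11930, with NCU09968 and NCU11930 listed at 0 in the mutant. In the limma model over 13 libraries, 177 genes responded to cellobiose against sucrose differently in the strains, 124 with a higher log2 difference in TBGK and 53 with a lower one, which can be a larger decrease, as in cel-1 (-6.74 in TBGK and -0.52 in WT). The count was 510.0 without Avicel replicate 1, 376 without sucrose replicate 1, 94 without Avicel replicate 2 or 3, 99 without sucrose replicate 2 and 88 without sucrose replicate 3. Of the set 48 had a higher and 2 a lower difference, with a median of 2.21 (2.06 to 2.23 with each sucrose replicate left out; the Avicel and no carbon libraries enter only the spread). The 48 became 80 without Avicel replicate 1, and 32 without Avicel replicate 3 or sucrose replicate 3. The interaction was 8.62 for cbh-1 (SE 1.32, adjusted p = 0.0171) and 6.27 for clr-2 (SE 0.78, adjusted p = 0.00743), both called with each of the 9 triplicate libraries left out, of which only the 3 on sucrose enter the size. The single libraries could not be left out. It did not pass for xlr-1 (2.56, SE 0.54, adjusted p = 0.0536; called without Avicel replicate 1, 0.0353, or sucrose replicate 1, 0.00751), clr-1 (1.03, SE 0.56, adjusted p = 0.408) or cre-1 (-2.08, SE 1.52, adjusted p = 0.55).

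TBGK and WT on sucrose were compared to see whether the deletions alter the repressed state. Cellulose genes stayed low in both: clr-2 was at 2.72 FPKM in TBGK against 2.43 ± 0.306, and cbh-1 at 32.4 against 32.7 ± 32.6. Of the set 33 genes were higher and 9 lower (median 0.12, percentile 99.8), with 30 to 42 higher when each sucrose replicate was left out. The set was chosen for low values in these same sucrose libraries, so this excess decides nothing. NCU08756 had the largest increase (8.96; 1468 FPKM against a WT mean of 2.74), and NCU09968, NCU09969 and NCU11930 were listed at 0 in the mutant and above 0 in every WT library. On Avicel, compared after the data were seen, 25 set genes were higher in TBGK and 36 lower (median -0.09, percentile 52.1; 17 to 37 higher with each Avicel replicate left out). By family, hemicellulases were higher in 5 and lower in 9 of 24 cases (median -0.72), cellobiose utilization genes higher in 3 and lower in 6 of 12 (median -0.97, with the 3 deleted genes among the 6) and LPMOs higher in 4 and lower in 0 of 14 (median 0.60). No difference between families was tested. NCU08756 was again the largest increase (9.79), followed by NCU07232 (6.61), and gh3-3, gh1-1 (-12.00), ccg-4, NCU09968 and the mating type gene matA-1 (NCU01958; 46.8, 283 and 337 in the WT) were the largest decreases, the last 3 listed at 0. Glycolysis and fermentation genes were higher in 8 of 12 cases, heat shock proteins in 7 of 10 and cytosolic ribosomal proteins in 7 of 7 (median 1.77), in lists where the first WT Avicel library stood apart: cfp (NCU02193), a pyruvate decarboxylase gene, was at 15862, 532 and 97.1 in the WT replicates and at 20520.3 in TBGK.

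**Figure D3:**
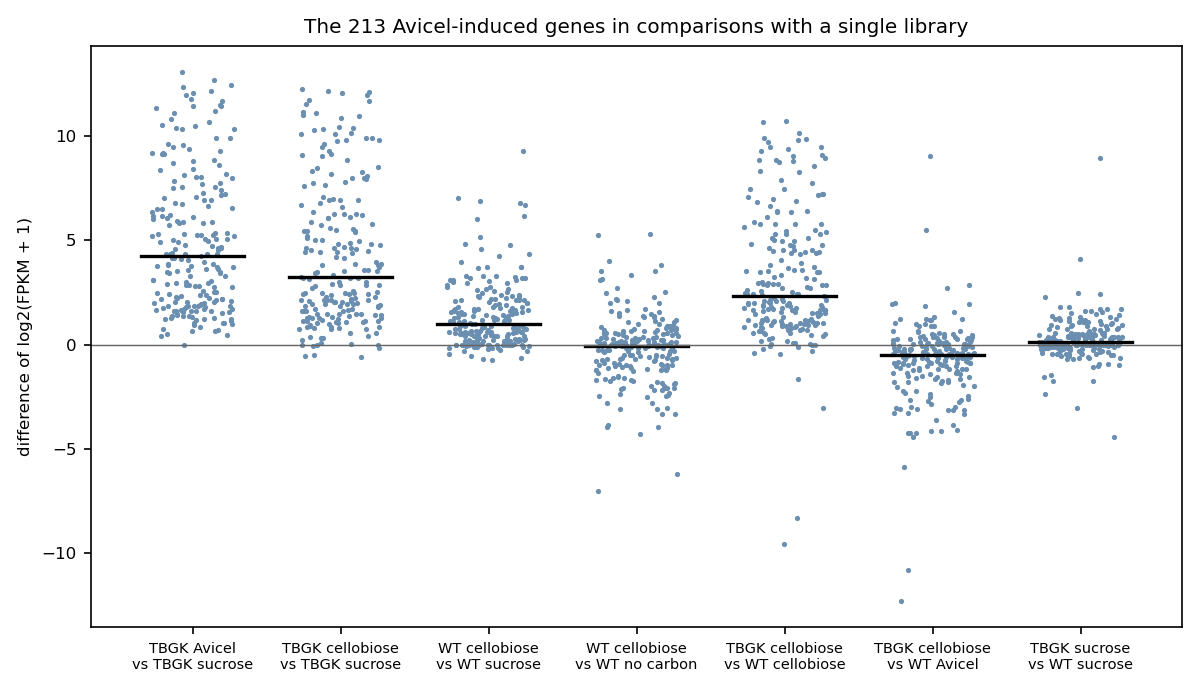
Log2 difference in FPKM + 1 for each of the 213 Avicel-induced genes (points) and their median (line) in 7 comparisons with single libraries. The median is 3.22 in TBGK on cellobiose against sucrose, 0.97 in WT on cellobiose against sucrose and 2.32 in TBGK against WT on cellobiose.

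One library of each WT group stood apart from its 2 replicates: Avicel replicate 1, no carbon replicate 2 and sucrose replicate 1. The genes that moved with them, chosen after values were seen, include cfp of fermentation, aod-1 of the alternative respiratory pathway, and NCU04276 and NCU11874, which have no symbol. In all 3 of these libraries 64 genes were at least 2-fold higher than the mean of the other 2 replicates of the group, taken on the log scale. Another 32 were at least 2-fold lower. FPKM of cfp was 15862 in Avicel replicate 1 against 532 and 97.1, 1914 in no carbon replicate 2 against 141 and 151, and 34410.4 in sucrose replicate 1 against 4347 and 2083. NCU04276 was at 65365 against 1761 and 42.2, at 21020.3 against 22.7 and 74.0, and at 19693 against 3101 and 2578 in the same order. None of these 4 genes was called by limma in any WT comparison. The 4 single libraries lay within the range of the 3 that stood apart, as did the other 2 sucrose libraries. The median of 61 such higher genes minus that of 22 lower ones, in log2, was 6.10 in WT on cellobiose and 6.36, 4.76 and 5.16 in TBGK on Avicel, cellobiose and sucrose. It was 6.17, 3.66 and 9.40 in the 3 libraries that stood apart, 0.96 and 0.47 in the other Avicel libraries, -0.82 and 0.07 in the other no carbon libraries and 3.69 and 3.71 in the other sucrose libraries. FPKM of cfp was 14533 to 24434 in the single libraries. Comparisons of a single library with the Avicel or no carbon triplicates may therefore include this difference. It cannot be told apart there from an effect of medium or strain, since the other 2 sucrose libraries also lay in the range.

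**Figure D4:**
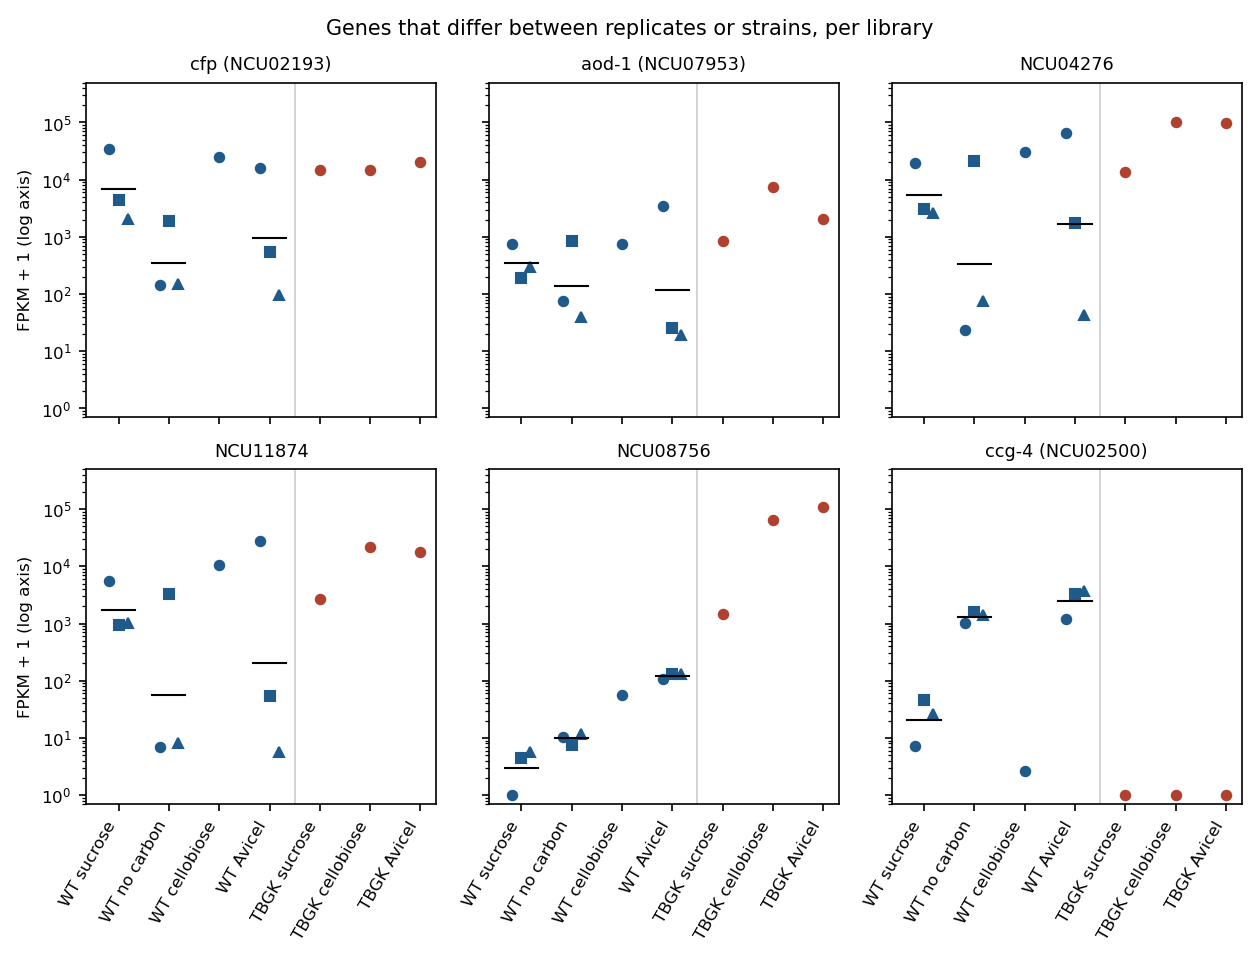
FPKM + 1 on a log axis in each library for cfp, aod-1, NCU04276, NCU11874, NCU08756 and ccg-4, with WT in blue and TBGK in red, circles, squares and triangles for replicates 1, 2 and 3, and a black line at the mean of the log values of 3 replicates. NCU11874 lies at 27419, 53.2 and 4.78 in the Avicel replicates, and NCU08756 at 108054 FPKM in TBGK on Avicel.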

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

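The tests of the lowest depth per group, of gh3-3 reads and gh3-3 sequence, of mating type and chromosome blocks, of other splits of the libraries and of the interactions with a WT library left out were chosen only after the result was seen; the tests of low depth and of an effect of every deletion on its neighbours were set earlier.

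The effect of a carbon source differed between the strains in a model with 1 library in 4 of its 7 groups. Cellobiose against sucrose differed between TBGK and WT in 177 genes, and Avicel against sucrose in 5. The limma model behind both assumes that a lone library varies like the WT triplicates, which nothing here can check. Only the triplicate libraries are marked as shared with an earlier deposit. The cellobiose against sucrose difference of the WT therefore spans deposits and that of TBGK does not. A difference between deposits would enter this interaction and cannot be told apart from one between strains. The interactions of cbh-1 and clr-2 passed with each of the 9 triplicate libraries left out, but only the 3 sucrose libraries enter their size, and the single libraries that carry them could not be left out. The counts moved widely: 177 became 510.0 without Avicel replicate 1 and 88 without sucrose replicate 3, and 5 became 507 without Avicel replicate 1, 227 without sucrose replicate 1 and 0 without Avicel replicate 2 or no carbon replicate 1. Neither count is firm, and the 5 genes do not show that the strains responded alike to Avicel.

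Splits of the 6 libraries into other groups of 3 gave at most 1 called gene for Avicel against no carbon (real value 493), 3 for Avicel against sucrose (5110) and 0 for no carbon against sucrose (5633). The 10 splits are too few for a share under 0.05. Each other split also mixed both media within its groups, so real differences between media widened its spread. Low counts were therefore built in, and these splits cannot decide on chance. Splits of all 9 libraries that mix media share this limit. For the Avicel-induced set, 3 of 100 splits of the 9 libraries, the real one with 213 genes included, gave a set as large. The other 2, with 1405 and 1380 genes, both took the 3 sucrose libraries as the group set against the rest, which points to the structure of the samples, and the next largest split gave 5.

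The first pattern is the library of each WT group that stood apart, with high cfp, NCU04276, NCU11874 and aod-1. Low depth of Avicel replicate 1 and sucrose replicate 1 would scatter weak transcripts and not abundant ones. Of 5004 genes with a mean FPKM of at least 100, the 3 libraries were all highest or all lowest of their groups for 23.3%. Independent libraries would give 7.41%, and the highest other trio gave 13.9%. The 3 libraries were chosen from these same values for standing apart. A high share was therefore built in, and the test cannot decide on low depth. The 4 single libraries lay within the range of these 3, so the pattern may also enter their comparisons with the Avicel and no carbon triplicates. Sucrose replicates 2 and 3 lay in that range too, so an effect of medium or strain cannot be told apart from it. Being the shallowest of its group is argued against for no carbon replicate 2, which has 2.63 times the depth of no carbon replicate 1. Avicel replicate 1 and sucrose replicate 1 are the shallowest of theirs. A shared difference in handling stays open and untested. No label gives a batch, or a culture condition that differs between replicates, and no biological explanation was tested.

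The second pattern is NCU08756, next to the deleted gh3-3, at 108054 FPKM in TBGK against a WT mean of 122 on Avicel. Reads of gh3-3 counted on it are argued against, because it was 888 times higher in the mutant where gh3-3 was listed at 0. A strong effect of every deletion on its neighbours, in the top 1% of differences, is argued against on Avicel only. Of the 5 other neighbours 1, NCU04953 beside gh3-4 (5.02 log2), was in that top 1%. Those of gh1-1 lay at percentiles 25.3 and 51.6 on Avicel. They lay at 57.1 and 87.6 on cellobiose and 88.2 and 87.5 on sucrose (1.07 and 1.03 log2). NCU08753 beside gh3-3 says little, at 1.89 FPKM in TBGK against 2.01 in the WT on Avicel and 0 in both on sucrose. A weaker effect at every deletion stays open, since every neighbour but NCU08753 was over 2-fold higher in TBGK on sucrose. Both neighbours of gh3-4 were higher in TBGK, with NCU04951 at 27063 against 7092 FPKM (percentile 94.7) on Avicel and at percentiles 97.1 and 98.6 on cellobiose and sucrose. Control by the sequence that drove gh3-3 alone is argued against too, because the Avicel minus sucrose difference of NCU08756 in the mutant was 4.33 log2 below that of gh3-3 in the WT (-4.33). Partial control stays open, since gh3-3 was at only 2.28, 10.1 and 2.82 FPKM in the WT on sucrose and the mutant had 1 library per medium. The same difference of NCU08756 was 6.20 in the mutant and 5.37 in the WT. A local effect at some or all of the deletions, such as from marker genes, may remain and was not tested, since that needs reads. Other differences between the strains stay open and untested.

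The third pattern is the 4 genes listed at 0 in all 3 mutant libraries and above 0 in all 10 WT libraries: ccg-4, NCU11930, NCU09968 and NCU09969. Of these, 2 are neighbours (NCU09968 and NCU09969 on supercont10.6, 309678 to 313666 and 314112 to 320071), a count of 2 that lies at percentile 99.85 of 10000 random draws, which is consistent with chromosome blocks that differ between the strains. Opposite mating type may account for ccg-4, a mating pheromone gene: the mat A genes reached at most 0 FPKM in the mutant, while matA-1 was at 46.8, 283 and 337 in the WT on Avicel and 12.3 on cellobiose. Low expression therefore does not account for the mutant values on Avicel. On sucrose matA-1 was at 0, 9.58 and 7.56 in the WT, and matA-2 was 0 in all 13 libraries, so these say little; a first, stricter form of the test, which asked for a mat A gene above 1 FPKM in every WT library, was not met for that reason. Whether mating type bears on the other 3 genes was not tested. The reverse, genes at 0 in all WT libraries and above 0 in all mutant ones, occurred 0 times. Strain background beyond the deletions stays open and untested.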

How the results depend on the processing

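The fits without the 2 shallowest libraries or with the first residual component as a covariate, the single-library comparisons and interactions with WT replicates left out, with only the WT library that stood apart or without the deleted genes, gene list tests under other scalings, and all values for TBGK on cellobiose against TBGK on Avicel and for TBGK against WT on Avicel, were tests chosen after seeing the data. The medians of the cellulases, LPMOs, hemicellulases, cellobiose utilization genes, regulators and ER folding genes stayed above 0 in both Avicel comparisons in every alternative run. Of 304 called results of named genes, 246 stayed called in the same direction in all alternatives and 58 did not. Over all alternatives 8040 values were the same, 266 lost the call, 79 gained it and 9 reversed. Most of these genes were named for large changes, so the share does not stand for all calls. For Avicel against no carbon, 261 of all 493 calls were kept without Avicel replicate 3.

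All 9 reversals were in WT no carbon vs WT sucrose under quantile normalization: clr-2 at -0.43, cdh-1 at -0.96 (not called in the main analysis), gh3-6 (NCU07487) at -1.32, gh7-1 at -0.041, gh7-4 at -0.93, NCU08176 at -0.57, gh18-8 (NCU07484) at -0.999, hH3 (NCU01635) at 1.08 and qa-2 (NCU06023) at -0.0047. Of these only cdh-1, gh3-6 and gh18-8 were called under quantile normalization. The cause was not tested.

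For WT Avicel vs WT no carbon the count of 493 was 908 without the 2 shallowest libraries (58.4% rises) and 1135 with the residual component (44.7% rises), against 69.4%; the cause was not tested. Leaving out single replicates gave 276 to 627, with fewer libraries as part of the cause. For WT Avicel vs WT sucrose that range was 4383 to 5492, for WT no carbon vs WT sucrose 4888 to 6065, and for the Avicel-induced set 157 to 230.0; all other alternatives of these 3 results stayed within 1.5 times. Gene list tests passed 36 times, and 9 times with an estimated correlation, which allows for genes that move together. With fry they passed 46 times. Fry does not set a list against other genes, so where most genes changed it answers another question.

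Counts of set genes higher in single-library comparisons depended on the threshold. With a fold minimum of 4, or with limma over 13 libraries, 103 became 57 or 47 for WT cellobiose vs WT sucrose, 34 became 17 or 20 for WT cellobiose vs WT no carbon, 17 became 5 or 5 for TBGK cellobiose vs WT Avicel, 33 became 5 or 2 for TBGK sucrose vs WT sucrose (12 with a pseudocount of 5), 7 became 2 or 0 for TBGK cellobiose vs TBGK Avicel (4 with a pseudocount of 5), and 25 became 7 or 3 for TBGK Avicel vs WT Avicel. With the set defined by a fold of at least 4 in both WT comparisons, which has 135 genes, 202 became 134 for TBGK Avicel vs TBGK sucrose. Leaving out WT replicates gave 102 to 103, 35 to 37, 13 to 23, 30 to 42 and 17 to 37 for the comparisons of WT cellobiose with WT sucrose and with no carbon, TBGK cellobiose with WT Avicel, TBGK with WT on sucrose, and TBGK with WT on Avicel. With only the WT library that stood apart, 17 became 8 for TBGK cellobiose vs WT Avicel and 25 became 15 for TBGK Avicel vs WT Avicel. Calls of the strain interactions ranged from 88 to 510.0 for cellobiose against sucrose and from 0 to 507 for Avicel against sucrose with WT replicates left out. Without the deleted genes, 183 of 211 set genes were higher in TBGK cellobiose vs TBGK sucrose.

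A replicate block gave 374, 4934 and 5529 calls in the 3 WT comparisons, 200.0 set genes and 37 list tests. The replicate numbers did not pair the libraries: of 9 pairs with the same number 4 had a correlation over 0.1 (range -0.31 to 0.45), and 4 of 9 libraries correlated best with their own number.

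Depth limits weak transcripts most in Avicel replicate 1 and sucrose replicate 1, where 1684 and 2341 genes were listed at 0. A gene listed at 0 there was not detected, and no limit can be given for such a value. Zeros did not follow depth alone. Sucrose replicates 2 and 3, at 2149.9 and 1942 aligned megabases, still had 1645 and 1842 genes at 0. The depth of the single libraries is unknown, so no limit can be given for their values of 0 either.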

Other observations

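The comparison of genes with the WT Avicel range, the genes in the next paragraphs and the view of sucrose replicate 2 were tests chosen only after the result was seen.

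Not every cellulose-responsive gene was at least 2-fold higher in TBGK on cellobiose. Of the 213 Avicel-induced genes 28 differed by less than 2-fold from TBGK on sucrose, and none of those with a symbol encodes a cellulase or hemicellulase. They include the ER chaperone grp78, at 6345 FPKM on cellobiose and 3249 on sucrose in TBGK but 14820.2 in TBGK on Avicel and 15979, 11826 and 13257 in WT on Avicel. Its difference between cellobiose and sucrose, 0.97 log2, lay just under the 2-fold cut. The glutathione transferase genes gst-3 (372 on cellobiose, 354 on sucrose) and gst-4 (187 and 158) were at 1597 and 581 in TBGK on Avicel. NCU05591, without a symbol, was at 81.1 on cellobiose, 84.8 on sucrose and 957 on Avicel in TBGK. NCU04475 was at 76.1 on cellobiose in TBGK against 2597, 5468 and 6115 in WT on Avicel, but only at 429 in TBGK on Avicel. Some of the 28 differed by less than 2-fold between Avicel and sucrose in TBGK too. Examples are vib-1 (708 on Avicel and 433 on sucrose) and NCU01856 (2895 and 1849). The 28 therefore do not all separate cellobiose from cellulose in this strain.

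In the WT, 34 of the 213 set genes (16.0%) were higher on cellobiose than on no carbon and 57 lower, in values of a single cellobiose library; of all 8759 tested genes 1386 (15.8%) were higher and 2281 lower. Among those higher were the following. The cellulase gh6-3 was at 3989 FPKM on cellobiose against a mean of 99.5 on no carbon, gh1-1 at 2632 against 189, gh3-3 at 3254 against 392 and the xylose reductase xr (NCU08384) at 590.4 against 92.0. The main cellobiohydrolase cbh-1 was at 246 against 114, where WT on Avicel had a mean of 125864.

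One sucrose library held more of the abundant Avicel transcripts than its replicates. In sucrose replicates 1, 2 and 3, FPKM was 11.2, 70.2 and 16.8 for cbh-1, 0, 66.9 and 5.07 for gh11-2, 5.58, 49.7 and 11.6 for cdt-2, and 0, 25.6 and 3.77 for gh5-1. No explanation was tested.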
